A study of Mus musculus with 24 samples.

How the data were processed

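Astrocytes were sorted by fluorescence from olfactory bulb, hippocampus, cortex and brainstem of 20-week-old mice. RNA was isolated with the RNeasy Micro kit, and libraries were made from 5 ng of total RNA with the NuGEN Trio RNA-Seq system. There were 24 libraries, 3 for each of 4 regions and 2 genotypes. The processing notes list FastQC, STAR 2.5.0a on mm10 and DESeq2 1.20.0, without saying what each was used for, and they name no counting tool, annotation or filter.

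The authors deposited 1 table of normalised signal per library, with 24421 gene names. Every value was checked to be a whole number of reads divided by 1 factor per library, within a tolerance of 0.01 read, so that reads could be recovered. The factors of the 6 cortical libraries equalled DESeq2-type median-of-ratios size factors over those libraries alone. The other 18 lay on a common scale, at 1.00 to 1.01 times joint factors of all 24 libraries, where the cortical factors were at 0.788 to 0.794 times. Comparisons within a region used the deposited values, and comparisons between control regions used recovered reads rescaled jointly over the 24 libraries. Recovered reads ranged from 1090777 to 24297573 per library. Of the names, 27 had been turned into dates and 2 were repeated, and 23350 matched symbols of the GENCODE vM21 annotation of mm10. Mitochondrially encoded genes had 0 entries and are not analysed here.

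Genes with a value of at least 20 in at least 3 libraries were tested, 12673 on the deposited scale and 12759 on the joint scale. Log2 of the value plus 5 was fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group of region and genotype, an intensity trend and robust variance moderation, which left 16 residual degrees of freedom. All tests were two-sided, and p was adjusted by Benjamini-Hochberg within each contrast with a threshold of 0.05. The contrasts were libraries labelled knockout against controls in each region, their average, an F test and single contrasts of differences of that effect among regions, and the controls of each region against the mean of the other 3. The last also required an absolute log2 fold change above 1. Adding 5 reduces the fold changes of genes at low levels.

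The groups, contrasts, thresholds, 40 gene lists, the rule for named genes and the alternatives were chosen before the data were examined. An edgeR quasi-likelihood test on counts with TMM factors had been planned as the main test. Because the deposited values are normalised, it was replaced after they were seen by limma with its added constant and low-value filter. The planned test was kept as an alternative on recovered reads, and called 29 genes in brainstem where limma called 98. Named genes were 12 nuclear factor I and astrocyte genes, and for each contrast the 10 higher and 10 lower genes with the largest log2 fold change among those past the threshold, with a mean CPM of at least 5 and no overlap between groups. Where fewer than 3 passed, the 5 with the smallest p were named. For the average and the F test these were the 10 with the smallest p, for control regions the 8 largest, and for each list described up to 4 members that passed. Unnamed gene models were skipped, and some genes named by this rule are not reported here.

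Lists with at least 5 tested genes, 38 in all, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. Where fewer genes than that were tested a list was left out. List counts are also given adjusted over the list alone. Alternatives were other low-value filters, edgeR 4.0.16 with TMM or RLE factors, DESeq2 1.42.0, limma-voom with sample weights, replicate numbers as blocks, voom with a correlation among libraries of the same genotype and number (the animal correlation, though no label names animals), a fold threshold added or removed, control libraries alone, the libraries of a region alone, and each library left out in turn. Those added after the data were seen were other added constants, reads thinned to equal depth with or without Rn45s, a choroid plexus covariate and deposited values without cortex. With a library left out, 2 remained in its group.

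Simulated counts held 100 changed genes at each fold per comparison. Each gene was drawn independently with the same dispersion in every region. Structure shared by genes of a library and the larger spread in brainstem were thus not simulated, and false calls from them are not counted here. The tests of single regions recovered 33 to 36 genes at a 2-fold and 62 to 73 at a 4-fold change. The average recovered 71 and 91, and the F test 11 and 62. Unchanged genes were also called, 8 in olfactory bulb, 12 in hippocampus, 6 in cortex and 12 in brainstem. The average called 9 unchanged genes and the F test 7. In each of these comparisons the unchanged genes were a larger share of the calls than the adjusted p threshold allows. The excess was largest in brainstem and hippocampus and slight in cortex and for the average. The p-values measure a spread between libraries that was estimated for each gene over all 24 libraries, not for each region. The median SD of log2 values was 0.39 and 0.41 in the brainstem groups and 0.27 to 0.33 in the other groups. The shared spread is thus smaller than that of most genes within brainstem, which favours calls there. The labels do not say whether libraries of different regions or numbers came from separate animals. Whether replicate numbers pair the libraries was unclear. Residuals correlated above 0.1 in 5 of 12 pairs of the same number within a region, and for 7 of 12 controls the closest library labelled knockout had the same number, among them all 3 in hippocampus (r = 0.27, 0.0375 and 0.32). Pairs were therefore used as an alternative only. Gene-level values span all exons, and the counting strand was not stated.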

Results

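The data were 24 bulk RNA-seq libraries from astrocytes sorted by fluorescence from 20-week-old C57BL6 mice. Astrocytes carried the Aldh1l1-GFP reporter, which marks cells with Aldh1l1 promoter activity. Control mice were NFIAfl/fl; Aldh1l1-GFP, and mice labelled knockout also carried Aldh1l1-CreER, a tamoxifen-inducible recombinase directed to astrocytes. Each genotype was profiled in olfactory bulb, hippocampus, cortex and brainstem, with 3 libraries in each of the 8 groups. The comparisons asked how removal of NFIA, a transcription factor of the nuclear factor I family, from adult astrocytes changed their transcriptome in each region, and how control astrocytes differed between regions. Reads recovered per library ranged from 4503269 to 9425474 in olfactory bulb, from 5543804 to 24297573 in hippocampus, from 3287872 to 7179349 in cortex and from 1090777 to 5552215 in brainstem. The brainstem library labelled knockout 3 was the shallowest. Levels are deposited normalised read counts, given as mean ± SD with n = 3 libraries, and log2 fold changes compare libraries labelled knockout with controls after adding 5 to each value.

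Nfia itself (chromosome 4, 97772734 to 98118874, plus strand of mm10), the targeted gene, gave more reads in the libraries labelled knockout than in controls of every region. Its level was 4528 ± 479 in controls and 8003 ± 566 in libraries labelled knockout of olfactory bulb, and 6216 ± 1495 and 11870 ± 1363 in hippocampus (SD, n = 3). In cortex it was 5081 ± 504 against 8367 ± 506, and in brainstem 4627 ± 1347 against 9666 ± 806 (SD, n = 3). All 12 libraries labelled knockout lay above every control of their region. The increase passed the limma test in hippocampus (log2 fold change 0.96, SE 0.18, adjusted p = 0.00327) and brainstem (1.10, SE 0.18, adjusted p = 0.00246). It did not pass in olfactory bulb (0.82, adjusted p = 0.0674) or cortex (0.72, adjusted p = 0.0847). Averaged over regions it was 0.90 (SE 0.09, adjusted p = 1.92e-07), and a difference in the effect among regions was not detected (adjusted p = 0.930). These counts cover the whole gene and cannot separate a deleted exon from the others, and their direction rests on the deposited labels. The brainstem call was lost when brainstem libraries were fitted alone, and the hippocampal call when a choroid plexus score was a covariate.

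**Figure D1:**
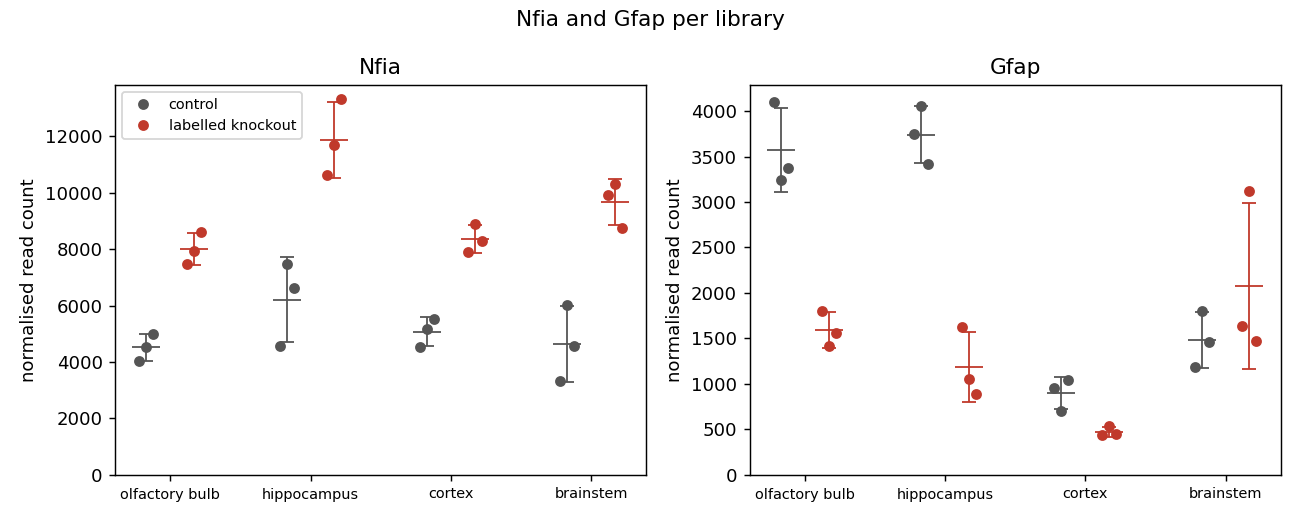
Deposited normalised read counts of Nfia and Gfap in each library, by region and genotype label, with the mean and SD of 3 libraries per group. All 12 libraries labelled knockout lie above the controls of their region for Nfia, and for Gfap the separation of the groups holds in 3 of the 4 regions.

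In olfactory bulb, Gfap (chromosome 11, 102887336 to 102900912, minus strand), the intermediate filament protein of astrocytes, fell from 3572 ± 465 to 1594 ± 198 in libraries labelled knockout, a 2.24-fold lower level (SD, n = 3). Clu, a secreted chaperone, fell from 9996 ± 2055 to 4580 ± 788, and Mfge8, a secreted protein that bridges dying cells to phagocytes, from 974 ± 104 to 402 ± 48.3. Apln, which encodes the peptide apelin, fell from 536 ± 79.2 to 107 ± 44.0, and Tprkb, a subunit of the KEOPS complex, from 1717 ± 320 to 553 ± 96.3. Dkk3, a secreted member of the Dickkopf family, rose from 868 ± 110 to 2080.5 ± 248, and the growth factor gene Fgf7 from 15.9 ± 1.97 to 122 ± 25.0.

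The limma test called 11 genes in olfactory bulb at a Benjamini-Hochberg adjusted p under 0.05, 2 higher and 9 lower in libraries labelled knockout. The log2 fold change was 1.26 for Dkk3 (SE 0.20, adjusted p = 0.00321), -2.34 for Apln (SE 0.30, adjusted p = 0.000273), -1.62 for Tprkb (SE 0.22, adjusted p = 0.000273) and -2.15 for Kcng4 (SE 0.35, adjusted p = 0.00491), a modifier subunit of voltage-gated potassium channels. Scara3, Gdpd2 and Fzd4 were the other lower genes, with log2 fold changes of -1.68, -2.08 and -1.28. Fewer than 3 genes passed in the higher direction, and the next by p were Trim23 (0.83, adjusted p = 0.0514), Nfia and Notch3 (1.29, adjusted p = 0.0714), none of which passed. The calls of Dkk3, Apln and Tprkb were kept whichever library of the region was left out. The call of Gfap (-1.16, adjusted p = 0.0395) was lost in all 6 such fits, with an adjusted p of at least 0.0801, as was that of Fgf7 (2.59, adjusted p = 0.0395), at least 0.0984. That of Mfge8 was lost unless the library labelled knockout 3 was the one left out (adjusted p of up to 0.117), that of Fzd4 unless control 2 was (up to 0.240), and that of Clu without control 2 or 3 or the library labelled knockout 1 or 2 (up to 0.133). Those of Gdpd2, Scara3 and Kcng4 were lost in 3, 3 and 2 of the 6 fits, with control 1 and the library labelled knockout 2 among the libraries left out for each. The count fell to 4, 7 or 6 without control 1, 2 or 3, and to 6 or 3 without the library labelled knockout 1 or 2. The lower genes were no longer the majority with voom (26 higher, 16 lower), with a correlation among libraries of the same genotype and number, the animal correlation (12 and 8), or with the region fitted alone (40 and 36).

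Among gene lists in olfactory bulb, 2 of 32 astrocyte core markers fell, Gfap and Clu, and 30 did not pass. Adjusted over the list alone, 4 fell, the median was -0.04, and camera did not call the list (adjusted p = 0.142). The 10 tested pan-reactive astrocyte genes had a median log2 fold change of -0.64, with 1 call, Gfap (2 adjusted over the list alone), and camera placed them below other genes (adjusted p = 0.00829, and adjusted p = 0.593 with an estimated correlation). Microglia markers had a median of -0.87 over 20 genes with 0 calls by limma (1 lower adjusted over the list alone; camera adjusted p = 1.09e-11, and adjusted p = 0.593 with an estimated correlation). Immediate early and dissociation response genes had a median of -0.81 over 29 genes, also with 0 calls (0 adjusted over the list alone; camera adjusted p = 3.64e-06, and adjusted p = 0.994 with an estimated correlation). Macrophage, oligodendrocyte and oligodendrocyte precursor markers had medians of -0.58, -0.39 and -0.31 with 0 calls by limma (1, 0 and 2 lower adjusted over the list alone). Their camera tests gave adjusted p = 0.0482, adjusted p = 0.0216 and adjusted p = 0.0312, and adjusted p = 0.994, adjusted p = 0.994 and adjusted p = 0.593 with an estimated correlation. Camera placed 2 lists above other genes, cholesterol biosynthesis with a median of 0.17 over 24 genes and 0 calls by limma (0 adjusted over the list alone; camera adjusted p = 0.00698, and adjusted p = 0.994 with an estimated correlation) and the Wnt pathway with a median of 0.21 over 22 genes and 1 call, Dkk3 (1 adjusted over the list alone; camera adjusted p = 0.0312, and adjusted p = 0.418 with an estimated correlation). The ribosomal RNA gene Rn45s took 20.8% of the reads of the olfactory bulb library labelled knockout 3 and between 2.14% and 3.33% of those of the other 5.

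In hippocampus, Gfap fell from 3740 ± 316 to 1188 ± 388 in libraries labelled knockout, a 3.15-fold lower level (SD, n = 3). Maob, the monoamine oxidase of astrocytes, fell from 1056 to 398, and Kcng4 was 11.9-fold lower. The glutamine transporter gene Slc38a3 went from 1113 to 2381, the glycine transporter gene Slc6a9 from 151 to 306 and the GABA transporter gene Slc6a11 from 4606 to 8877. The genes with the largest decreases included several known from the choroid plexus, the epithelium that makes cerebrospinal fluid. Among these, Prlr, the prolactin receptor gene, fell from 2714 ± 749 to 48.1 ± 16.9, Enpp2, which encodes autotaxin, from 58497 ± 21265 to 2089 ± 961, and Kl, which encodes klotho, from 4114 ± 1676 to 165 ± 69.1 (SD, n = 3).

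The limma test called 318 genes in hippocampus, 91 higher and 227 lower in libraries labelled knockout. Gfap had a log2 fold change of -1.70 (SE 0.23, adjusted p = 0.000171), Maob of -1.40 (SE 0.18, adjusted p = 6.43e-05) and Kcng4 of -2.64 (SE 0.35, adjusted p = 0.000101). Tex15, a gene best known from male germ cells, had 0 reads in the 3 controls and a mean of 63.6 ± 6.38 in libraries labelled knockout, at least 113-fold higher against a floor of 3 reads over the group (adjusted p = 6.43e-05). The other genes with the largest increases had log2 fold changes between 1.88 and 2.21, and were Gabrg3, Rgs16, Ermap, Fam84a, Pdzph1, Igsf21, Slc22a15, Klhl15 and Prss23. The largest decreases, of between -4.53 and -5.70, were in Prlr, Lbp, Slc4a5, Col8a1, Kcnj13, Tmem72, Enpp2, Folr1, Kl and F5. Of the 63 genes named for hippocampus and called, 21 were called in every fit that left out 1 hippocampal library, among them Gfap, Maob, Kcng4, Tex15, Nfia, Fam84a, Klhl15, Lbp and Slc4a5. The call of Prlr was lost without control 1 or the library labelled knockout 3 (adjusted p of up to 0.0705), that of Enpp2 in 4 of the 6 fits (up to 0.0885) and that of Kl in all 6 (up to 0.166).

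The count in hippocampus rested in part on single libraries. It was 90 without control 1, and 190, 171 and 101 without the libraries labelled knockout 1, 2 and 3. Ttr, the thyroid hormone carrier gene of the choroid plexus, lay between 66790 and 134843 in hippocampal controls and between 2010 and 5660 in libraries labelled knockout. Its log2 fold change of -5.08 (SE 1.37) did not pass (adjusted p = 0.0619). With the mean log2 level of 5 choroid plexus genes as a covariate, a fit added after the data were seen, 10 genes were called. This loss of calls does not show its reason, since the score lay at 11.1 or more in hippocampal controls and at 7.68 or less in libraries labelled knockout. The standard errors of that fit alone, with the log2 fold changes of the fit without the score, left 88 calls. Its log2 fold changes alone, with the standard errors of the fit without the score, gave 350. The log2 fold change of Gfap with the score was -1.43 (SE 0.34, adjusted p = 0.154), and the calls of Nfia, Tex15 and Maob were lost, while those of Kcng4 and Klhl15 were kept.

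**Figure D2:**
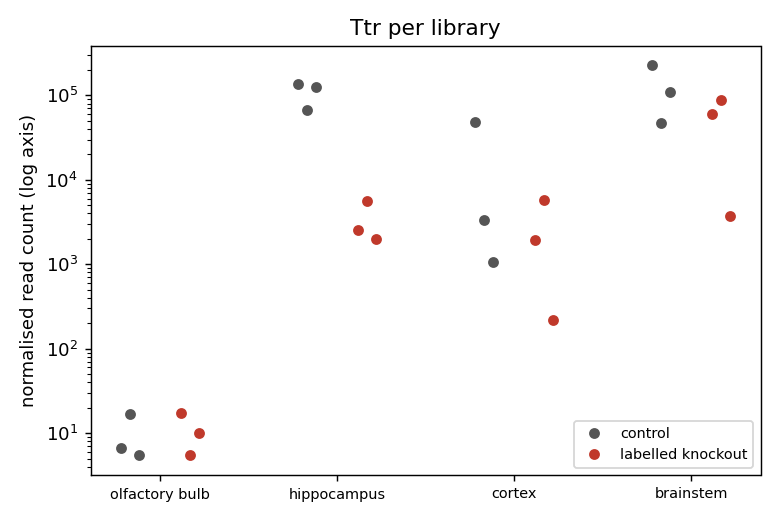
Deposited normalised read counts of Ttr in each library on a log axis, by region and genotype label. Hippocampal controls lie between 66790 and 134843, hippocampal libraries labelled knockout between 2010 and 5660, and brainstem control 1 is highest at 225951.

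Among gene lists in hippocampus, 4 of 26 genes of glutamate, GABA and glycine handling rose, among them Slc38a3, Slc6a9 and Slc6a11, and 2 fell, among them Maob. Adjusted over the list alone these were 6 and 4, and camera did not call the list (adjusted p = 0.441). Of 32 astrocyte core markers 1, Aldh1l1, rose and 1, Gfap, fell, against 6 and 1 adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.000670, and adjusted p = 0.841 with an estimated correlation). The call of Aldh1l1, whose name the CreER transgene of mice labelled knockout bears, was lost in 3 of the 6 fits with a hippocampal library left out. Of 35 tested genes of the nuclear factor I family and astrocyte transcription factors 3 rose, namely Nfia, Sall3 (log2 fold change 0.99) and Tcf7l2 (0.73), and 0 fell. Adjusted over the list alone these were 3 and 0 (camera adjusted p = 4.65e-07, and adjusted p = 0.144 with an estimated correlation). Of 29 genes of lipid transport and fatty acid metabolism 3 rose, the fatty acid binding genes Fabp5 (1.32) and Fabp7 (0.97) and the elongase gene Elovl2 (0.76). Adjusted over the list alone 6 rose (camera adjusted p = 0.000965, and adjusted p = 0.602 with an estimated correlation). Of 32 secreted synapse regulators 2 rose, Chrdl1 (1.29) and Ptn (0.92), and 2 fell, Thbs4 (-2.41) and the complement gene C4b (-1.39), against 3 and 4 adjusted over the list alone, with a median of 0.0482 but a mean of -0.11 (camera adjusted p = 0.668). Of 13 tested ependymal and choroid plexus markers 5 fell, or 10 adjusted over the list alone, with a median of -3.17 (camera adjusted p = 3.16e-15, and adjusted p = 0.0998 with an estimated correlation). Oligodendrocyte markers had a median of -0.78 over 16 genes with 0 calls by limma (0 adjusted over the list alone; camera adjusted p = 2.30e-05, and adjusted p = 0.494 with an estimated correlation). Macrophage markers had a median of -0.99 over 12 genes with 0 calls by limma (1 lower adjusted over the list alone; camera adjusted p = 0.000965, and adjusted p = 0.494 with an estimated correlation). The calls of Sall3, Tcf7l2, Slc6a9, Slc6a11 and Fabp7 were each lost in 3 of the 6 fits with a hippocampal library left out, and those of Elovl2 and C4b in 4. Control 1 and the library labelled knockout 3 were among these libraries for each gene, and adjusted p values went up to 0.0928 for Sall3, 0.239 for Tcf7l2 and higher for Elovl2.

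In cortex, Kcng4 was 21.7-fold lower in libraries labelled knockout, at 3.43 ± 2.35 against 74.3 ± 27.9, and Maob fell from 830.5 ± 45.0 to 286 ± 50.4 (SD, n = 3). Hsd11b1, whose enzyme regenerates active glucocorticoid, fell from 375 ± 74.9 to 83.5 ± 14.2, and Entpd2, an ecto-ATPase gene, from 248 ± 36.7 to 57.8 ± 3.77. Kcnip3, which encodes a potassium channel interacting protein, fell from 1118 ± 135 to 389 ± 46.6. Tex15 rose from 5.25 ± 6.06 to 78.5 ± 40.9, Slc6a9 from 161 ± 42.2 to 373 ± 39.5, and Robo2, a receptor for Slit guidance cues, from 320.4 ± 76.1 to 719 ± 122. Gfap was 901 ± 176 in controls and 473 ± 53.1 in libraries labelled knockout, and did not pass.

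The limma test called 41 genes in cortex, 13 higher and 28 lower in libraries labelled knockout. The log2 fold change was -3.22 for Kcng4 (SE 0.35, adjusted p = 8.91e-06), -1.54 for Maob (SE 0.18, adjusted p = 1.07e-05), -2.10 for Hsd11b1 (SE 0.27, adjusted p = 8.37e-05), -1.51 for Kcnip3 (SE 0.21, adjusted p = 0.000185) and 3.05 for Tex15 (SE 0.48, adjusted p = 0.00113). That of Gfap was -0.91 (SE 0.23, unadjusted p = 0.000560), which did not pass after adjustment. The other genes with the largest increases were Fgfbp3, Prss23, Fam84a, Ifit3b, Notch3, Spata13 and Vim, at 1.12 to 2.26. The other genes with the largest decreases were Hhatl, Extl1, Gfpt2, Slc24a3 and Cyp2d22, at -1.47 to -2.94. Of the 27 genes named for cortex and called, 9 were called whichever cortical library was left out, among them Kcng4, Maob, Hsd11b1, Entpd2, Kcnip3, Hhatl, Fam84a and Tex15. Leaving out cortical control 1, 2 or 3 gave 25, 16 or 21 genes, and leaving out the library labelled knockout 1, 2 or 3 gave 19, 19 or 18. The call of Slc6a9 was lost without control 2 or the library labelled knockout 1 (adjusted p of up to 0.0827), and that of Robo2 without control 1 or the library labelled knockout 2 (up to 0.0718).

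Among gene lists in cortex, Clu was the 1 call among 32 astrocyte core markers, with a log2 fold change of -1.14, and 2 members fell adjusted over the list alone (camera adjusted p = 0.00580, and adjusted p = 0.842 with an estimated correlation). Of 26 genes of the Notch and BMP pathways 1 rose, the receptor gene Notch3 (1.36), and 2 rose adjusted over the list alone (camera adjusted p = 0.00294, and adjusted p = 0.202 with an estimated correlation). Of 13 neuroblast and immature neuron markers 1 rose, Robo2 (1.17), and 1 adjusted over the list alone, with a median of 0.69 (camera adjusted p = 6.13e-06, and adjusted p = 0.202 with an estimated correlation). Among pan-reactive genes 1 of 10 rose and 0 fell, or 1 and 2 adjusted over the list alone, with a median of -0.27, and camera did not call the list (adjusted p = 0.514). The 1 call, of the filament gene Vim (1.12, adjusted p = 0.0488), was lost with any cortical library left out, at an adjusted p of up to 0.361. That of Notch3 was lost in 5 of the 6 such fits (up to 0.161), and that of Clu without control 2 or the library labelled knockout 1 (up to 0.0515). Endothelial markers had a median of 0.79 over 16 genes with 0 calls by limma (0 adjusted over the list alone; camera adjusted p = 0.000937, and adjusted p = 0.713 with an estimated correlation). Ependymal and choroid plexus markers had a median of -0.89 over 13 genes, neuron markers of -0.29 over 26 and oligodendrocyte precursor markers of -0.30 over 14, with 0 calls by limma in any of them, also adjusted over each list alone. Their camera tests gave adjusted p = 0.00369, adjusted p = 0.0315 and adjusted p = 0.0386, and adjusted p = 0.597, adjusted p = 0.713 and adjusted p = 0.597 with an estimated correlation. Ttr was 48254 in cortical control 1 and between 218 and 5769 in the other 5 cortical libraries.

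In brainstem, Dkk3 rose from 90.6 ± 30.0 to 291 ± 65.2, and Notch3 from 177 ± 29.3 to 526 ± 183 in libraries labelled knockout (SD, n = 3). The astrocyte genes Aqp4, the water channel gene, and Nfix, a further nuclear factor I gene, rose from 14264 to 25977 and from 2111 to 3323. Chrdl1, which encodes a secreted antagonist of BMP, rose from a level of 5.30 to 32.2, and the potassium channel gene Kcnk2 from 62.6 to 176. Rcor1, a corepressor gene, fell from 110 ± 47.0 to 23.1 ± 20.2, and Med16, a Mediator subunit gene, from 169 ± 16.9 to 68.9 ± 18.8. Gfap was 1483 ± 313 in controls and 2076 ± 912 in libraries labelled knockout, with overlapping values.

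The limma test called 98 genes in brainstem, 69 higher and 29 lower in libraries labelled knockout. The log2 fold change was 1.66 for Dkk3 (SE 0.20, adjusted p = 2.62e-05), 1.81 for Chrdl1 (SE 0.20, adjusted p = 1.25e-05), 1.49 for Notch3 (SE 0.28, adjusted p = 0.0105), 0.94 for Aqp4 (SE 0.21, adjusted p = 0.0296) and 0.65 for Nfix (SE 0.15, adjusted p = 0.0356). That of Gfap was 0.42 (SE 0.23, adjusted p = 0.399). The other genes with the largest increases were Pdzph1, Slc39a8, Masp1, Ptchd4, Amacr, Txlnb, Hapln1 and Ptchd2, at 1.47 to 2.03. The other genes with the largest decreases were Hs6st2, Myo19, Taf12, Pcsk2, Usp28, Mdfic, Tmem218 and Mtch1, at -1.17 to -2.07. Of the 36 genes named for brainstem and called, 8 were called whichever brainstem library was left out, among them Nfia, Dkk3, Chrdl1, Fam84a, Ptchd4 and Txlnb. The calls of Aqp4 and Nfix were lost without control 1, control 3 or the library labelled knockout 1, and also without that labelled knockout 3 for Aqp4 and 2 for Nfix (adjusted p of up to 0.227 for each). Those of Notch3, Rcor1 and Med16 were lost without the library labelled knockout 3, that of Notch3 also without control 1, and that of Rcor1 also without control 1 or the library labelled knockout 2 (up to 0.0936, 0.172 and 0.0513).

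The brainstem count depended on single libraries. It was 17 without control 1, 892 without control 2, 39 without control 3, and 205 and 22 without the libraries labelled knockout 2 and 3. Its direction did too, with 52 higher and 60 lower without the library labelled knockout 1, and 94 higher and 111 lower without that labelled knockout 2. Fitting the brainstem libraries alone with limma gave 0 calls and 818 genes at an unadjusted p under 0.05, whereas fits of all 24 libraries gave 29 calls by edgeR and 170 by DESeq2. Ttr was 225951 in brainstem control 1, 47066 and 110909 in controls 2 and 3, and 60215, 87460 and 3683 in the libraries labelled knockout 1, 2 and 3.

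Among gene lists in brainstem, 3 of 32 secreted synapse regulators rose, Chrdl1, Ptn (log2 fold change 0.81) and Hapln1 (1.54), and 0 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.000861, and adjusted p = 0.242 with an estimated correlation). Of 32 astrocyte core markers 1 rose, Aqp4, and 0 fell, against 4 and 0 adjusted over the list alone, with a median of 0.41 (camera adjusted p = 1.30e-06, and adjusted p = 0.468 with an estimated correlation). Of 25 genes of potassium, ion and water handling 2 rose, Kcnk2 (1.45) and Aqp4, against 5 adjusted over the list alone (camera adjusted p = 0.000669, and adjusted p = 0.242 with an estimated correlation). Of 35 genes of astrocyte morphology and adhesion 1 rose, Cadm1 (1.00), and 0 fell, against 13 and 2 adjusted over the list alone (camera adjusted p = 1.30e-06, and adjusted p = 0.242 with an estimated correlation). Of 22 Wnt pathway genes 2 rose, Dkk3 and the receptor gene Fzd1 (1.36), and 3 adjusted over the list alone, and camera did not call the list (adjusted p = 0.0663). Ependymal and choroid plexus markers had a median of -1.64 over 13 genes with 0 calls by limma (0 adjusted over the list alone; camera adjusted p = 0.000175, and adjusted p = 0.283 with an estimated correlation). Without control 1 or the library labelled knockout 3 the calls of Kcnk2, Cadm1 and Ptn were lost, that of Ptn also without control 3, with adjusted p values of up to 0.146. That of Hapln1 was lost without control 3 or the library labelled knockout 2 or 3 (up to 0.113).

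Averaged over the 4 regions, Kcng4 and Maob were lower in every library labelled knockout than the control mean of its region, with average log2 fold changes of -2.11 (SE 0.18, adjusted p = 1.93e-08) and -1.01 (SE 0.09, adjusted p = 2.46e-08). Fam184a (0.86), Fam84a (1.47), Chrdl1 (1.02), Nfia (0.90) and Notch3 (1.27) were above the control mean in all 12 libraries labelled knockout. Hhatl (-2.13) and Cryab (-1.04), a small heat shock protein gene, fell, and Dkk3 rose by 0.89 on average. Of the other nuclear factor I genes, Nfib rose by 0.41 (adjusted p = 0.00152), Nfic by 0.26 (adjusted p = 0.0306) and Nfix by 0.26 (adjusted p = 0.0401) on the log2 scale.

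The limma test of the average called 745 genes, 354 higher and 391 lower in libraries labelled knockout, and 1293 without brainstem control 2. Higher genes were the majority with voom (439 higher, 341 lower), with the animal correlation (290 and 210) and without brainstem control 2 (671 and 622) or hippocampal control 3 (368 and 363). Among the astrocyte genes fixed for naming, Aldh1l1 (average log2 fold change 0.50, adjusted p = 0.00230), Slc1a3 (0.66, adjusted p = 0.0112), Kcnj10 (0.47, adjusted p = 0.0191) and Aqp4 (0.39, adjusted p = 0.0252) passed. Slc1a2 (-0.02, adjusted p = 0.970), Gja1 (0.23, adjusted p = 0.203) and Sox9 (0.04, adjusted p = 0.886) did not. Only mice labelled knockout carried Aldh1l1-CreER, and whether this transgene added to the reads of Aldh1l1 was not settled, as given below. With the choroid plexus covariate 78 genes were called.

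Among gene lists, 8 of 35 genes of the nuclear factor I family and astrocyte transcription factors rose on average and 0 fell. Nfia, Nfib, Nfic and Nfix were among the 8. Adjusted over the list alone 11 rose and 1 fell (camera adjusted p = 1.09e-05, and adjusted p = 0.167 with an estimated correlation). Of 24 cholesterol biosynthesis genes 6 rose and 0 fell, against 11 and 0 adjusted over the list alone (camera adjusted p = 1.67e-05, and adjusted p = 0.508 with an estimated correlation). Of 35 genes of astrocyte morphology and adhesion 6 rose and 0 fell, against 8 and 0 adjusted over the list alone (camera adjusted p = 8.90e-06, and adjusted p = 0.392 with an estimated correlation). Of 22 Wnt pathway genes 6 rose, against 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00738, and adjusted p = 0.106 with an estimated correlation). Ependymal and choroid plexus markers had 7 of 13 lower, or 10 adjusted over the list alone (camera adjusted p = 7.83e-10, and adjusted p = 0.107 with an estimated correlation). Oligodendrocyte markers had a median of -0.30 over 16 genes with 1 lower (1 adjusted over the list alone; camera adjusted p = 0.00425, and adjusted p = 0.681 with an estimated correlation). Microglia markers had a median of -0.28 over 20 genes with 1 higher (1 adjusted over the list alone; camera adjusted p = 0.0224, and adjusted p = 0.868 with an estimated correlation). Camera called 12 of 38 tested lists for the average (9 higher and 3 lower), 8 in olfactory bulb (2 and 6), 14 in hippocampus (9 and 5), 12 in cortex (7 and 5) and 13 in brainstem (11 and 2), lists not described here included. With an estimated correlation 0 of these calls held. A test by fry, which does not compare a list with other genes, called 7 lists for the average, 3 in hippocampus and 10 in brainstem, and no list in olfactory bulb or cortex.

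**Figure D3:**
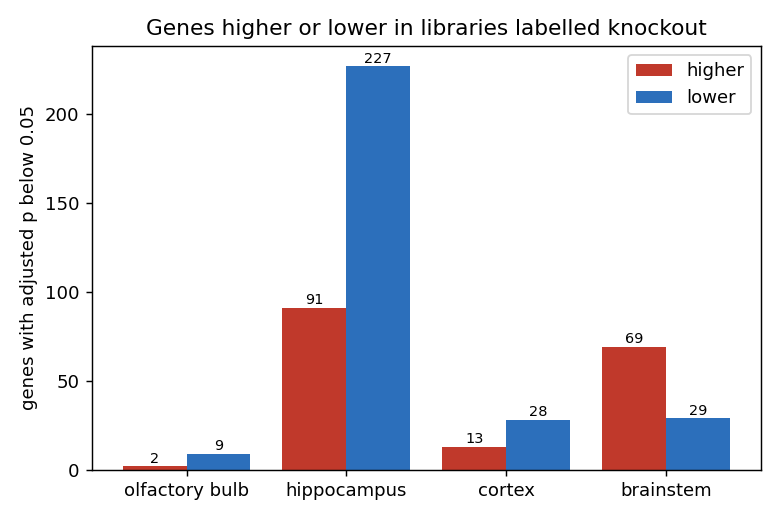
Number of genes called higher and lower in libraries labelled knockout in each region by limma at an adjusted p under 0.05. Hippocampus had 318 calls, brainstem 98, cortex 41 and olfactory bulb 11.

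By limma's F test the effect of the knockout label differed among regions for Gfap, whose log2 fold change was negative in olfactory bulb, hippocampus and cortex and 0.42 in brainstem. Other splits of the libraries, given below, did not exclude chance for this test or for the differences of single regions. The brainstem effect exceeded the mean of the other regions by 1.68 (SE 0.27, adjusted p = 0.0123). Slc14a1, a urea transporter gene, had log2 fold changes of -1.28 in cortex, 0.85 in brainstem, 0.45 in olfactory bulb and -0.09 in hippocampus. Kcnip3 had a log2 fold change of -1.51 in cortex against a mean of -0.16 elsewhere. Tex15 rose in hippocampus and cortex, with a log2 fold change of 1.64 in olfactory bulb (adjusted p = 0.305) and -0.07 in brainstem.

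The limma F test of a difference among regions called 7 genes, Slc14a1, Gfap, Igfbp5, Tprkb and Dkk3 (each with adjusted p = 0.0298) and Tex15 and Hsd11b1 (each with adjusted p = 0.0383). Of the next genes by p, Kcnip3 (adjusted p = 0.0504), Rasgef1a and Kcng4 (each with adjusted p = 0.0598) did not pass. Against the mean of the other regions, 2 genes had another effect in cortex, Kcnip3 (-1.35, SE 0.24, adjusted p = 0.0296) and Slc14a1 (-1.69, SE 0.26, adjusted p = 0.00941), and 21 in brainstem, 12 higher and 9 lower. Limma called 0 genes for olfactory bulb, with 654 at an unadjusted p under 0.05, where edgeR called 1 and DESeq2 4. It called 0 for hippocampus, with 784 at an unadjusted p under 0.05, where edgeR called 0 and DESeq2 40. The brainstem count was 0 without brainstem control 1, 244 without brainstem control 2, 5 without brainstem control 3, 46 without the brainstem library labelled knockout 1, 13 without that labelled knockout 3 and 36 without hippocampal control 1. It was 12 without olfactory bulb control 3 and 13 without the hippocampal library labelled knockout 1 or the cortical library labelled knockout 2. The count of 7 fell to 0 without olfactory bulb control 3, the olfactory bulb library labelled knockout 1, the hippocampal library labelled knockout 2, cortical control 2 or 3 or the cortical library labelled knockout 3, and rose to 89 without brainstem control 2 and 34 without cortical control 1. The cortical count was 0 without cortical control 2 or 3 or the library labelled knockout 3.

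Genes called in several regions were few. Fam184a, Fam84a, Fat4, a protocadherin gene, and Ifit3b, an interferon-induced gene, were called higher in hippocampus, cortex and brainstem, and Kcng4 and Tprkb lower in olfactory bulb, hippocampus and cortex. Of these, Fat4 was chosen after its values were seen. With each library of a region left out in turn, only Fam84a kept all 3 calls in every fit. The calls of Ifit3b were lost in all 6 fits in cortex and 4 of 6 in brainstem, and those of Fat4 in 6, 5 and 3 of 6 in hippocampus, cortex and brainstem (adjusted p of up to 0.239). Those of Tprkb were lost in 3 of 6 in hippocampus and 4 of 6 in cortex, that of Kcng4 in 2 in olfactory bulb and that of Fam184a in 2 in cortex. A further 42 genes were called in 2 regions, 366 in 1 and 0 in all 4 by limma, and 0 were called in opposite directions in any pair of regions. Hippocampus and brainstem shared 21 higher genes, where 0.496 would be shared by chance with independent calls, and hippocampus and cortex shared 13 lower genes against 0.502. Across 12673 genes, which are not independent replicates, the correlation of log2 fold changes between regions ranged from 0.07 for olfactory bulb and brainstem to 0.40 for hippocampus and brainstem (Pearson), or from 0.08 to 0.31 (Spearman), over the 6 pairs of regions. The genes called in a region had the same sign in the other 3 for 7 of 11 in olfactory bulb, 202 of 318 in hippocampus, 28 of 41 in cortex and 53 of 98 in brainstem, where 12.5% would by chance if regions were independent. Ttr had log2 fold changes of -5.08 in hippocampus, -2.02 in cortex, -1.97 in brainstem and 0.14 in olfactory bulb, none of which passed. Whether a difference in choroid plexus RNA common to several regions underlies shared calls or correlations was not tested.

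Control libraries of the 4 regions differed in patterning genes and in markers of other cells (given below), so the differences cannot be assigned to astrocytes alone. In olfactory bulb, the neuropeptide gene Npy had a level of 766 ± 169 and the Wnt antagonist gene Frzb of 718 ± 62.0, against at most 12.3 and 17.8 in the other regions (SD, n = 3, jointly rescaled reads). The transcription factor genes Dmrt3 and Fezf2 were highest in hippocampus, at 53.1 ± 11.8 and 269.6 ± 88.0, and Hopx was at 3055 ± 810. Lhx2 was at 2044 ± 207 in cortex, 1546 ± 263 in hippocampus, 1266 ± 185 in olfactory bulb and 4.12 ± 3.44 in brainstem. Dkk3 was at 4113 ± 111 in cortex, 1866 ± 412 in hippocampus, 866 ± 110 in olfactory bulb and 90.1 ± 29.9 in brainstem. In brainstem, Cyp26b1, a retinoic acid degrading enzyme gene, was at 857 ± 446 and Dao, the D-amino acid oxidase gene, at 296 ± 108. Gfap was at 3561 ± 461 in olfactory bulb and 3724 ± 315 in hippocampus, and at 1141 ± 223 in cortex and 1475 ± 312 in brainstem.

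The limma test with an absolute log2 fold change above 1 called 1095 control genes in olfactory bulb against the mean of the other regions (570 higher, 525 lower), 221 in hippocampus (93 higher, 128 lower), 445 in cortex (225 higher, 220 lower) and 1252 in brainstem (709 higher, 543 lower). The cortical count was 253 without cortical control 2 and 287 without cortical control 3. Higher genes were the majority in hippocampus with voom (184 higher, 70 lower) and with edgeR (129 and 117 with TMM, 126 and 117 with RLE). Log2 fold changes were 6.20 for Npy and 5.67 for Frzb in olfactory bulb, followed by Clca3a1, Sp8, Cdhr1, Tex15, Mybpc1 and Omp at 4.90 to 5.62. In hippocampus they were 3.82 for Thbs4, 3.14 for Dmrt3 and 2.76 for Fezf2, followed by Neurod6, Slit1, Icosl, Hopx and Nr2f1 at 1.36 to 2.76. In cortex they were 3.79 for Crym, 3.39 for Car8 and 3.20 for Rpe65, and lay between 2.51 and 2.99 for Lhx2, Dkk3, Myom3 and Tbr1. In brainstem they were 5.75 for Cyp26b1 and 5.59 for Dao, followed by Lpo, Klk6, Irx5, Nefh, Gria4 and Foxb1 at 3.36 to 3.86. Among astrocyte genes fixed for naming, the glutamate transporter gene Slc1a3 differed by -2.66 in brainstem (adjusted p = 4.48e-08) and Gfap by 1.05 in hippocampus (adjusted p = 0.00130) and -1.24 in cortex (adjusted p = 7.52e-05). For Nfia, differences between regions were not detected, with adjusted p from 0.140 to 0.482.

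Gene lists of regional patterning separated the control groups. Of 12 ventral forebrain and olfactory bulb factors 9 were higher in olfactory bulb and 1 lower (11 and 1 adjusted over the list alone), and of 13 olfactory ensheathing and sensory markers 10 were higher (10 adjusted over the list alone). Both camera calls held with an estimated correlation, at adjusted p = 0.00972 and adjusted p = 2.96e-05. Dorsal forebrain factors had 6 of 15 higher in hippocampus and 9 of 15 in cortex (7 and 9 adjusted over the list alone, with 1 lower in each), with adjusted p = 2.46e-05 and adjusted p = 0.000154 with an estimated correlation. In brainstem 10 of these 15 were lower and 2 higher (11 and 2 adjusted over the list alone), and 9 of 10 hindbrain factors were higher (9 adjusted over the list alone, with 1 lower), each with adjusted p = 7.76e-05 with an estimated correlation. Neural stem and progenitor markers were lower in brainstem for 6 of 12 genes (6 adjusted over the list alone), with adjusted p = 0.00328 with an estimated correlation. Oligodendrocyte markers were higher in brainstem for 13 of 17 genes (14 adjusted over the list alone; camera adjusted p = 3.06e-08, and adjusted p = 0.258 with an estimated correlation), and 8 of 13 ependymal and choroid plexus markers were higher there (9 adjusted over the list alone; camera adjusted p = 1.48e-06, and adjusted p = 0.198 with an estimated correlation).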

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

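The tests of mislabelled libraries, exchanged labels, astrocyte share, read depth, errors of the covariate fit and libraries left out of corrected counts were chosen after the results were seen, and the splits of the libraries and the tests on the choroid plexus score were set before theirs.

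The effect of the knockout label differed among regions by limma's F test for Slc14a1, Gfap, Igfbp5, Tprkb and Dkk3 (adjusted p = 0.0298 for each) and for Tex15 and Hsd11b1 (adjusted p = 0.0383 for each). Log2 fold changes in olfactory bulb, hippocampus, cortex and brainstem were -0.34, -1.56, -1.24 and 0.41 for Igfbp5, -1.62, -0.92, -1.13 and 0.27 for Tprkb, 1.26, 0.65, -0.02 and 1.66 for Dkk3, and -1.07, -1.35, -2.10 and 0.21 for Hsd11b1. Of 100 splits of the libraries within regions, 5 gave at least the 7 genes of this test, the real split included, and the highest other gave 567, so chance was not excluded. The count was 0 without any 1 of 6 libraries and 89 without brainstem control 2. In cortex 2 genes, Kcnip3 and Slc14a1, had another effect than in the other regions, and 3 of 100 splits gave as many, with the highest other at 3. This share was under 0.05, but cortex was 1 of 4 regions tested alike and another split gave more genes, so chance was not excluded. The cortical count was also 0 without cortical control 2 or 3 or the library labelled knockout 3. It was 0 by limma without a low-value filter (796 at an unadjusted p under 0.05, edgeR 1, DESeq2 9). In brainstem 21 genes did, among them the thyroid hormone deiodinase gene Dio2 (difference 1.33), Med16 (-1.42), Rasgef1a (-2.43) and the imprinted genes Peg10 (-1.58) and Dlk1 (-3.66), of which Dio2, Peg10 and Dlk1 were chosen after their values were seen. Here 12 of 100 splits gave as many and the highest other gave 578, so chance was not excluded, and the count was 0 without brainstem control 1 and 244 without brainstem control 2. Limma called 0 genes for olfactory bulb (654 at an unadjusted p under 0.05, edgeR 1, DESeq2 4) and for hippocampus (784, edgeR 0, DESeq2 40), where a count of 0 is reached by all 100 splits by construction, so that these say nothing about chance, and the highest others gave 1 and 768. Splits with counts as high as these point to a structure of the libraries other than the genotype label.

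Nfia gave more reads in the libraries labelled knockout, by 0.90 on average on the log2 scale. Single mislabelled libraries were argued against, since 0 of the 12 libraries labelled knockout lay at or below the highest control of their region. A higher share of astrocytes was argued against as the whole cause, since 31 other astrocyte markers had a median average log2 fold change of 0.15 with an interquartile range of 0.33. The astrocyte core list had higher medians in hippocampus and brainstem, where Nfia passed, so a higher share there as part of the cause was not excluded. An exchange of all labels stays open, because the direction within a region cannot be told apart from it by these values. Of 12179 windows of 3 neighbouring tested genes, 4 had all 3 genes called higher on average in libraries labelled knockout by limma at an adjusted p under 0.05. Aldh1l1, Slc41a3 and Iqsec1 formed 1 of these windows, as might be seen if those libraries carried the CreER transgene with flanking sequence, which the labels do not describe. The neighbour Klf15 was at 0.17 (adjusted p = 0.523). Continued or increased transcription of a recombined allele is a biological explanation that was not tested, as the values do not separate exons.

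The 227 genes lower in hippocampal libraries labelled knockout may stem in part from choroid plexus RNA in the controls. Over the 18 libraries of other regions, the slope on a score of 5 choroid plexus genes (Ttr, Kl, Folr1, Clic6 and Prlr) predicted at least 50% of the hippocampal log2 fold change for 125 of them (55.1%), against 42.1% of all genes with a negative hippocampal log2 fold change. The score was followed by 129 of them (56.8%), the score genes that were called included, against 7.03% of the tested genes. With the score as a covariate their median log2 fold change went from -2.01 to -0.84 while the median SE went from 0.48 to 0.59, but this does not tell why calls ended, since the scores of the 2 genotypes did not overlap in hippocampus and the larger errors alone took the 318 calls to 88. An effect of genotype on choroid plexus cells themselves was not tested, and sorting for GFP would be expected to remove cells without the reporter.

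Hippocampus had 318 calls where the other regions had at most 98, and stayed above 1.5 times the others in 21 of 24 fits with a library left out, but not without hippocampal control 1, the hippocampal library labelled knockout 3 or brainstem control 2. Depth was argued against as the whole cause, since with every library thinned to equal depth hippocampus had a median of 231 calls over 10 draws (202 to 269) and the highest other median was 41, and with reads other than Rn45s thinned alike, since Rn45s took more reads in cortex and brainstem, it had 212 (191 to 237) against at most 37.5, and the first draw of each kept this in all 21 of those fits. Choroid plexus RNA as the cause cannot be told apart from an effect of genotype. Without the genes that followed the score 189 remained against at most 90 elsewhere, which met the bound set beforehand against it and did so in 20 of the 21 fits, but this was not taken to exclude it, a choice made after the value was seen, because the bound was missed without the hippocampal library labelled knockout 2 (98 against 76) and 68 of the 98 remaining lower genes (69.4%) still had a slope above 0, against 44.6% of other tested genes, while without every lower gene with such a slope 121 remained against at most 75. A stronger effect of the knockout label in hippocampus stays open as well, where loss of NFIA itself is not shown by the Nfia reads. Against the mean of the other regions limma called 0 genes (784 at an unadjusted p under 0.05, edgeR 0, DESeq2 40). It called 17 without cortical control 1 and 8 without brainstem control 1. With replicate numbers as a block it called 25, but this assumes the same animals in all regions, and Ddx3y goes against that for some numbers.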

How the results depend on the processing

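Fits with added constants of 1 and 20, the choroid plexus covariate, thinned reads with or without Rn45s and deposited values without cortex were chosen after the data were seen. The main limma fit was too, in place of the planned edgeR test with TMM.

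The average count stayed within 1.5 times of 745 under all alternatives except the covariate (78), thinned reads (477.5, or 457.5 without Rn45s) and leaving out brainstem control 2. The control region counts did so except as given below. Of 137 named calls, 123 and 132 were kept with constants of 1 and 20, 93 without a low-value filter, 103 with edgeR, 129 of 130 with DESeq2, 98 with voom, 91 with the animal correlation, 93 with the region alone and 44 with the covariate. In the shallowest library, the brainstem library labelled knockout 3, 1 read stands for 5.75 normalised units, so that levels of a few reads are not resolved there. Unless stated, the cause of a change was not tested, and fits with a library left out also have fewer samples.

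Counts for libraries labelled knockout in olfactory bulb (11) were 22 with a constant of 20, 56 with DESeq2, 42 with voom, 20 with the animal correlation, 76 with the region alone and 22 with the covariate. In hippocampus (318) they were 642 with DESeq2, 1095 with the animal correlation and 10 with the covariate. In cortex (41) they were 22 without a filter, which tested more genes, 93 with DESeq2, 117 with voom, 23 with the animal correlation and 142 with the region alone. In brainstem (98) they were 29 with edgeR and TMM, 33 with RLE, 170 with DESeq2, 53 with voom, 7 with the animal correlation, 0 with the region alone by limma (818 at an unadjusted p under 0.05), 62 with a fold threshold, 14 with the covariate and 41 with thinned reads, or 37.5 without Rn45s.

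The F test (7) gave 12 with a constant of 1, 0 without a filter by limma (1302 at an unadjusted p under 0.05), 15 with edgeR under TMM and RLE and 86 with DESeq2. Differences of a region from the others were 1 with TMM, 1 with RLE, 4 with DESeq2 and 2 with voom in olfactory bulb (0), and 1 with a constant of 1 and 40 with DESeq2 in hippocampus (0). They were 0 without a filter by limma (796 at an unadjusted p under 0.05), 1 with TMM and 9 with DESeq2 in cortex (2), and 10 without a filter, 12 with TMM, 12 with RLE, 58 with DESeq2 and 13 with voom in brainstem (21).

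With a replicate block, which assumes pairs the labels do not state, counts were 19 in olfactory bulb, 33 for the F test, and 1, 25 and 32 for the difference in olfactory bulb, hippocampus and brainstem. The animal correlation, estimated at 0.0177, takes libraries of the same genotype and number in all regions as 1 animal, which the labels do not state. The Y-linked gene Ddx3y goes against that for some numbers, at 778 in brainstem control 3 and 0 in control 3 of the other regions, and at 720 and 590 in the libraries labelled knockout 1 of olfactory bulb and hippocampus and 0 in those of cortex and brainstem. Counts with it, and the block for differences among regions, which assumes the same animals, are therefore no evidence on pairing.

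Control region counts without a fold threshold, a looser criterion, were 1809, 365, 871 and 2246 in olfactory bulb, hippocampus, cortex and brainstem. In hippocampus (221) they were 354 with DESeq2 and 492 with deposited values without cortex, which compares with 2 regions. The majority direction of control genes turned in olfactory bulb with DESeq2 (632 higher, 661 lower), deposited values without cortex (584 and 648) and without olfactory bulb control 1 (466 and 475), hippocampal control 3 (536 and 541) or brainstem control 2 (605 and 618). It turned in cortex with DESeq2 (244 and 246), the block (225 and 274) and 4 of 12 controls left out. In brainstem it turned without a fold threshold (1054 and 1192) and without brainstem control 1 (419 and 432) or 3 (492 and 539).

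With 1 library of the same region left out, counts ranged from 3 to 9 in olfactory bulb, 90 to 251 in hippocampus, 16 to 25 in cortex and 17 to 892 in brainstem. With any of the 24 libraries left out, which also changes the variance estimate of the other regions, they ranged from 3 to 27, 90 to 467, 16 to 65 and 17 to 892, the 27 and 467 without brainstem control 2 and the 65 without brainstem control 1. They then ranged from 539 to 1293 for the average and 0 to 89 for the F test. Differences ranged from 0 to 5 in olfactory bulb, 0 to 17 in hippocampus, 0 to 6 in cortex and 0 to 244 in brainstem, and control counts from 253 to 563 in cortex.

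Log2 fold changes that changed sign with the covariate were those of Kl (0.0535), F5 (0.0930), Aqp4 (-0.0069) and Slc1a2 (-0.44) in hippocampus, Aqp4 (-0.0228) and Dkk3 (0.0451) in cortex, and Hsd11b1 (-0.0485) and Kcnip3 (-0.0529) in brainstem. Of these, Kl and F5 had been called. In brainstem Sox9 was 0.0541 with voom and 0.0209 with the animal correlation, and Tex15 4e-04 with a constant of 20 and 0.0835 with voom.

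With 1 library left out, log2 fold changes that did not pass ranged across 0 in olfactory bulb for Aqp4 (-0.0340 to 0.12), Gja1 (-0.19 to 0.13), Sox9 (-0.21 to 0.10) and Fam84a (-0.0072 to 0.29). They did so in hippocampus for Slc1a2 (-0.16 to 0.24), Slc14a1 (-0.21 to 0.0213) and Kcnip3 (-0.37 to 0.0242), and in cortex for Nfix (-0.14 to 0.0011) and Dkk3 (-0.0492 to 0.0222). In brainstem they did so for Slc1a2 (-0.0069 to 0.87), Sox9 (-0.11 to 0.13), Cryab (-0.33 to 0.11), Tex15 (-0.64 to 0.33) and Kcnip3 (-0.10 to 0.45).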

Other observations

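The splits reported here were set before their results were seen, and the reading of sex-linked and ribosomal genes was chosen afterwards.

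Members of further gene lists passed the test in hippocampus, while the lists as a whole were not called with an estimated correlation. Of 25 interferon response and antigen presentation genes, Ifit3 rose (64.6 to 178) and Ifi27 (314 to 111) and Stat2 (154 to 62.5) fell in libraries labelled knockout by limma, or 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0409, and adjusted p = 0.850 with an estimated correlation). Among 12 neural stem and progenitor markers, Fabp7 was among those that rose (1019 to 1996) and Thbs4 fell (208 to 35.8), and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0229, and adjusted p = 0.144 with an estimated correlation). These calls rested on single hippocampal libraries. Without control 1 those of Ifit3, Ifi27, Stat2 and Fabp7 were lost, where Fabp7 had an adjusted p of 0.117. Leaving out the library labelled knockout 2 lost those of Ifit3, Ifi27, Stat2, Fabp7 and Thbs4 (adjusted p = 0.0506 for Thbs4). Leaving out that labelled knockout 3 lost those of Ifit3, Ifi27, Stat2 and Fabp7. Ifi27 was also lost without the library labelled knockout 1, and Stat2 without control 2 or 3.

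With the libraries of a region split otherwise into 3 against 3, the highest other count was 0 in olfactory bulb, hippocampus and cortex by limma, against real counts of 11, 318 and 41, and only 1 of 10 splits, the real one, gave as many. In brainstem 3 of 10 splits gave at least 98, and the highest gave 671. The 10 splits are too few for a share under 0.05. The brainstem split with 671 set control 1, control 3 and the library labelled knockout 2, which had the 3 highest Ttr values, against the other 3, which points to a structure of the libraries. For the average, 1 of 100 splits, the real one, gave as many as 745, and the highest other gave 2. This excludes chance only if libraries of different regions came from separate animals, which the labels do not state.

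For control regions, chance was excluded in olfactory bulb and brainstem if libraries of different regions came from separate animals, which the labels do not state. It was not excluded in hippocampus or cortex. In olfactory bulb 1 of 100 splits gave as many as 1095, with the highest other at 785, and in brainstem 1 of 99 gave as many as 1252, with the highest other at 731. A further split, with 906, regrouped other regions but kept the 3 brainstem controls together, and was left out as no other split of brainstem. In hippocampus 3 of 100 gave at least 221, with the highest other at 986, and in cortex 3 of 100 gave at least 445, with the highest other at 816. The split with 986 put the 3 brainstem controls in place of hippocampus, and that with 816 the 3 olfactory bulb controls in place of cortex, so that these counts came from differences between regions. Splits that grouped hippocampal control 1 with brainstem controls 1 and 3 gave 785, 755, 758 and 731 genes in place of olfactory bulb, hippocampus, cortex and brainstem, which points to a structure of these 3 libraries. Their 755 and 758 exceeded the real counts of 221 in hippocampus and 445 in cortex, without being differences between whole regions. The share of 3 of 100 was under 0.05 in both, but 4 regions were tested alike. Chance was therefore not excluded for hippocampus and cortex.

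Rn45s took 13.5% to 25.6% of recovered reads in the 12 cortical and brainstem libraries, and 0.966% to 3.33% in those of olfactory bulb and hippocampus apart from the olfactory bulb library labelled knockout 3 at 20.8%. The Y-linked gene Ddx3y was between 576 and 778 in control 1 and the library labelled knockout 1 of olfactory bulb and hippocampus, cortical control 1 and brainstem control 3, and at 0 in the other 18 libraries. Sex was thus mixed within groups. In cortex and brainstem only controls held a library with Ddx3y, so sex was not balanced between the labels there, nor in the tests of differences among regions.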
